A study of Macaca mulatta with 36 samples.

How the data were processed

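The series holds 36 Affymetrix rhesus arrays of hippocampal total RNA from 18 male macaques, with 2 arrays, labelled technical replicates, for each of 9 SIVE animals and 9 uninfected controls. The series design speaks of duplicate samples of tissue, and whether these are separate pieces is not given in the sources used here. The deposited values are on a log2 scale, read from their range, which ends at 14.49, and were made with RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set, per the submitters' processing notes. The version of RMA is not given in the sources used here, nor are its probe definitions. The array medians lie between 5.59 and 5.75, and no column lacked a sample. Arrays give no counts, so the number of arrays limits the precision.

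The table has 52865 probe sets. Left out were 99 Affymetrix control probe sets and 59 reporter gene probe sets, 158 in all; the reporter sets were added to those left out after seeing the data. The other 52707 were tested. Gene symbols came from the table that pairs probe set IDs with names: 24969 probe sets have 1 symbol, 361 several and 27535 none. For gene-level results each gene was represented by the probe set with the highest mean over all arrays, among probe sets with 1 symbol, which gave 14132 genes.

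The 2 arrays of an animal were averaged on the log2 scale and counted as 1 replicate. Differences were tested per probe set with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided) with Benjamini-Hochberg adjustment over all 52707 probe sets and a threshold of 0.05. SIVE was compared with control over all 18 animals. The other comparisons used 1 mean for each combination of group and anti-CD8 label (4 treated and 5 untreated SIVE animals, 2 treated and 7 untreated controls) with a shared spread. They were SIVE against control without anti-CD8 and with it, the difference between these effects, and anti-CD8 against none within SIVE and within control animals. The replicate numbers were checked for pairing and do not pair the animals, so no block was used.

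Genes named in the text follow a rule: those past the threshold whose higher group mean reached the median probe set level of 5.65, the 12 largest rises and 12 largest falls in SIVE against control and the 5 and 5 largest in each other comparison, without uncharacterised genes. Added to these were EGR1, virus probe sets, CD8A and CD8B in the anti-CD8 comparisons, and in each list the 4 members with the smallest adjusted p. Other list members, the single probe set called in treated SIVE animals and the further probe sets with sequence accessions were chosen after their values were seen. This rule, the comparisons, the tests and 31 gene lists with 550 members were fixed before the data were examined, and 375 list members were measured.

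The function lists were interferon-stimulated genes, MHC class I and antigen processing, MHC class II, complement, chemokines and cytokines, retrovirus entry and restriction factors, tryptophan and pterin metabolism, immediate early genes, glutamatergic synapse, mitochondrial respiratory chain, heat shock and hypoxia, unfolded protein response, cell cycle, and cytosolic ribosomal proteins. The cell type lists were homeostatic microglia, macrophage and myeloid, T cell, CD8 and cytotoxic lymphocyte, B and plasma cell, neuron, inhibitory neuron, astrocyte, reactive astrocyte, oligodendrocyte, oligodendrocyte precursor, endothelial cell and pericyte, choroid plexus and ependyma, red blood cell, dentate granule cell, pyramidal cell, and striatum and thalamus. Lists were tested with limma's camera with a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the 31 lists. Fry tested whether a list's genes move, on balance, in 1 direction, without comparing them with other genes. A list score of an animal is the mean over its members of the difference from the control mean, and the virus score is the same mean over the 5 of the 9 virus probe sets that were called higher in SIVE, a choice that rests on the result.

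Relations between scores used Pearson's r and Spearman's rho over the 9 SIVE animals with exact permutation tests. Single measures were compared between groups with exact two-sided permutation tests. The 3′ minus 5′ difference is the mean over GAPDH, ACTB and EEF1A1 of the log2 signal of the 3′ control probe set minus that of the 5′ one. Permutation tests, tables and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

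The limma step was tested on simulated data with 52707 probe sets and known changes. For SIVE against control it recovered 70.1% of 1.5-fold, 92.5% of 2-fold and 98.5% of 4-fold changes, and 4.92% of its calls were false. For animals without anti-CD8 it recovered 59.7%, 89.6% and 97.0%, with 6.82% of calls false. For animals with anti-CD8 it recovered 40.3%, 67.2% and 98.5%, with 6.80% false. For anti-CD8 against none it recovered 43.3%, 77.6% and 100% in SIVE animals, with 3.92% of calls false. In controls it recovered 38.8%, 74.6% and 95.5%, with 6.71% false. A simulated list of 15 genes shifted by 0.5 was called by camera with both correlations and by fry, and 0 of 30 unchanged lists were called by any of these 3. The simulated noise was drawn separately for each probe set. It holds no correlation between genes, so these shares do not show how the tests behave with such correlation. It also gives every animal the same spread. The shares can thus be too high for comparisons that rest on animals of poorer array quality, as those with anti-CD8 do.

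Alternatives were other scalings of the arrays (medians set equal, quantile normalization), a filter on dim probe sets, averaging the probe sets of a gene, each technical replicate alone, all 36 arrays with the animal as a random block, a variance trend with robust estimation, array weights, covariates for anti-CD8 and age, the replicate number as a block, only the animals compared, and leaving out each animal in turn. After seeing the data, 3 more were added: leaving out the 3 animals of high 3′ signal, the 3′ difference as a covariate, and leaving out the second array of Control 9.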

Results

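RNA from the hippocampus of 18 male rhesus macaques was hybridized to Affymetrix arrays, with 2 arrays per animal and 36 arrays in all. Simian immunodeficiency virus encephalitis (SIVE), a brain inflammation seen in macaques infected with simian immunodeficiency virus, was recorded in 9 animals, and 9 uninfected animals served as controls. The labels also record an anti-CD8 treatment, an antibody used in macaques to remove CD8 T cells, in 4 SIVE animals and 2 controls. The other 5 SIVE animals and 7 controls are labelled as not treated. SIVE animals were 2 to 6 years old and controls 3 to 8 years old, and the 4 treated SIVE animals were all 6 years old. The log2 values of 52865 probe sets reach 14.49, and the array medians lie between 5.59 and 5.75. Duplicate arrays of an animal differed by a median SD of 0.146 (log2), against 0.191 between the 2-array means of the animals of a group. The sources used here do not state whether the 2 arrays read 1 RNA or separate tissue pieces, so this SD can hold tissue sampling as well as array noise. Their correlation across probe sets was 0.976 in Control 9, and 0.992 to 0.997 in the other 17 animals. The 2 arrays of an animal were averaged, so the number of animals limits the precision, with a median SE of 0.0885 for the SIVE difference.

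The first 2 principal components held 37.3% and 23.2% of the variance between animals. On component 2 the SIVE animals lay between 15.7 and 41.9 and the controls between -48.5 and -21.8, so the groups did not overlap. On component 1, SIVE 2, SIVE 3 and Control 8 lay between 64.1 and 105.5, and the other 15 animals between -52.3 and 19.6. The same 3 animals had the largest 3′ minus 5′ signal difference of the control transcripts GAPDH, ACTB and EEF1A1, a sign of shortened RNA or short labelled copies. It was 0.948 to 1.46 (log2) in these 3 and 0.105 to 0.465 in the other 15. All 3 carry the anti-CD8 label. The mean difference was 0.692 ± 0.583 (SD, n = 6) with anti-CD8 and 0.296 ± 0.0820 (SD, n = 12) without it (exact permutation p = 0.0246, two-sided). This test was chosen after the 3′ signal was seen, and its result rests on SIVE 2, SIVE 3 and Control 8. The other treated animals, SIVE 1 (0.105), Control 9 (0.167) and SIVE 4 (0.279), lay below the mean without anti-CD8. Between SIVE (0.440 ± 0.374, n = 9) and control animals (0.416 ± 0.399, n = 9) the exact permutation p was 0.924.

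**Figure D1:**
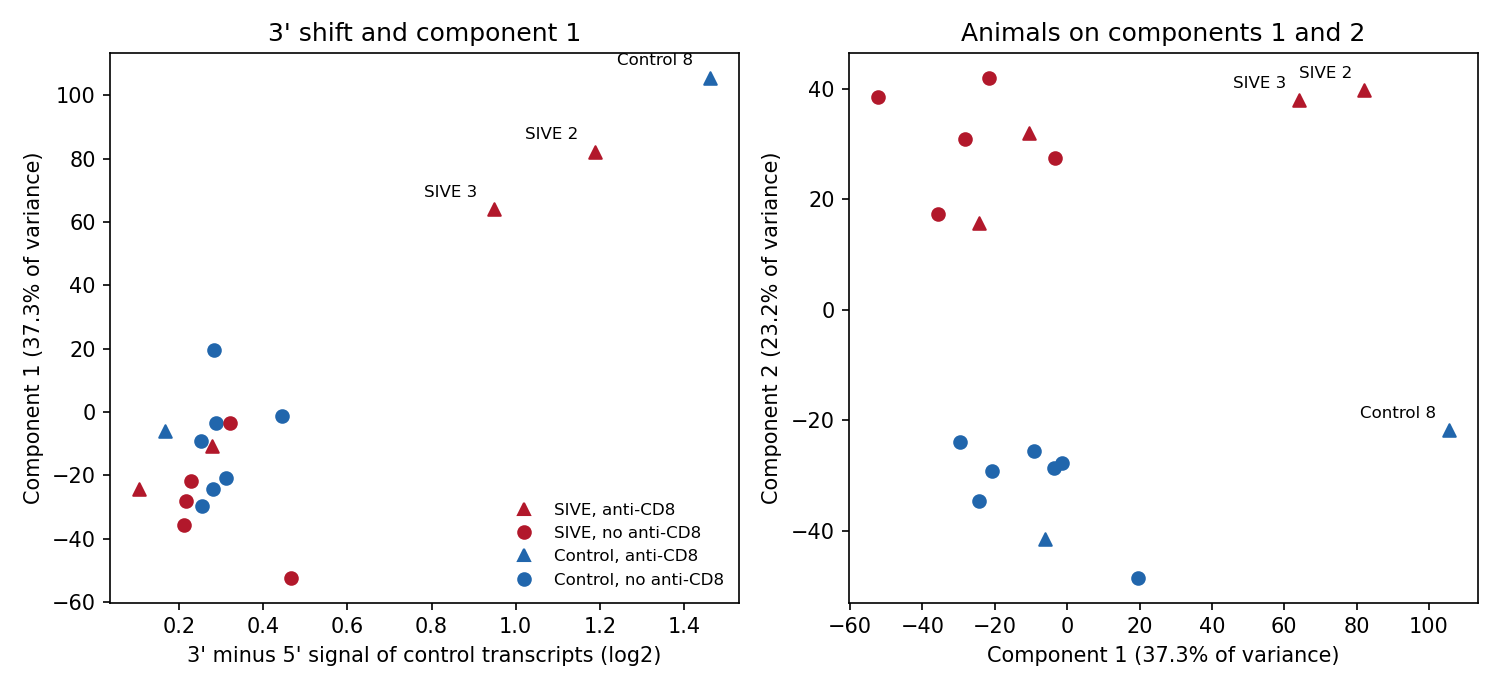
Left, the score of each of the 18 animals on component 1 against the 3′ minus 5′ signal difference of the control transcripts (log2). Right, the scores on components 1 and 2, with SIVE in red, controls in blue, and triangles for animals labelled anti-CD8. SIVE 2, SIVE 3 and Control 8 lie apart at 0.948 or more on the 3′ measure.

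The main comparison asked which transcripts differ in the hippocampus between macaques with SIVE and uninfected controls. The series holds no infected animals without encephalitis, so effects of infection and of encephalitis cannot be told apart. Genes induced by interferon and chemokine genes rose most in SIVE. ISG15, a ubiquitin-like protein induced by interferon, was at 12.18 ± 0.49 (SD, n = 9) in SIVE and 6.80 ± 0.37 (n = 9) in controls, a rise of 5.37 ± 0.19 (SE, log2), or 41.5-fold. CXCL10, a chemokine that attracts T cells, rose by 5.19 ± 0.34, or 36.5-fold, from 4.70 ± 0.19 to 9.89 ± 1.09. CCL2 and CCL8, chemokines that attract monocytes, rose 21.5-fold and 21.0-fold. IFI27 rose 22.5-fold, the antiviral GTPase MX1 22.4-fold, IFI44 21.9-fold, the RNA sensor IFIH1 16.8-fold, IFIT3 14.8-fold and HERC6 12.8-fold. SERPINA3, an acute-phase protease inhibitor made by reactive astrocytes, rose 17.5-fold, and 2 of its 4 other probe sets moved the same way. AMBP, the precursor of a plasma carrier protein and a protease inhibitor, rose 13.9-fold, but its other probe set did not move with it. For each of these 12 genes all 9 SIVE animals lay above all 9 controls. The control means of CXCL10, CCL2, CCL8, IFIH1 and AMBP lay below the median probe set level of 5.65, and a fold against a signal that dim can understate the change.

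The 12 largest falls were smaller than the 12 largest rises. HES5, a transcription factor downstream of Notch, fell by 1.12 ± 0.17 (SE, log2) from 7.95 ± 0.28 (SD, n = 9) to 6.83 ± 0.48 (n = 9) and was 2.17-fold lower. DUSP1, a phosphatase induced by cell activity and stress, fell by 0.92 ± 0.22, and the nuclear receptor NR4A1, another early response gene, by 0.86 ± 0.15. IGSF1 fell by 0.88 ± 0.14, TNNT1 by 0.81 ± 0.19, the DNA replication checkpoint gene CLSPN by 0.81 ± 0.13, ADSS1 by 0.75 ± 0.15 and FOXQ1 by 0.70 ± 0.13. EGFL8 fell by 0.74 ± 0.20 and CRP, C-reactive protein, by 0.72 ± 0.19. PAQR6 fell by 0.86 ± 0.18 at its brightest probe set, and its other probe set had the opposite sign. TRIM22, an antiviral gene induced by interferon, fell by 0.79 ± 0.18 at its brightest probe set, while its other probe set passed the threshold in the opposite direction. With the probe sets of TRIM22 averaged it was higher in SIVE by 0.64 (limma adjusted p = 0.0111), and PAQR6 no longer passed. DUSP1, TNNT1, TRIM22 and CRP did not pass with the replicate number as a block, and EGFL8 and CRP did not pass without several single animals.

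**Figure D2:**
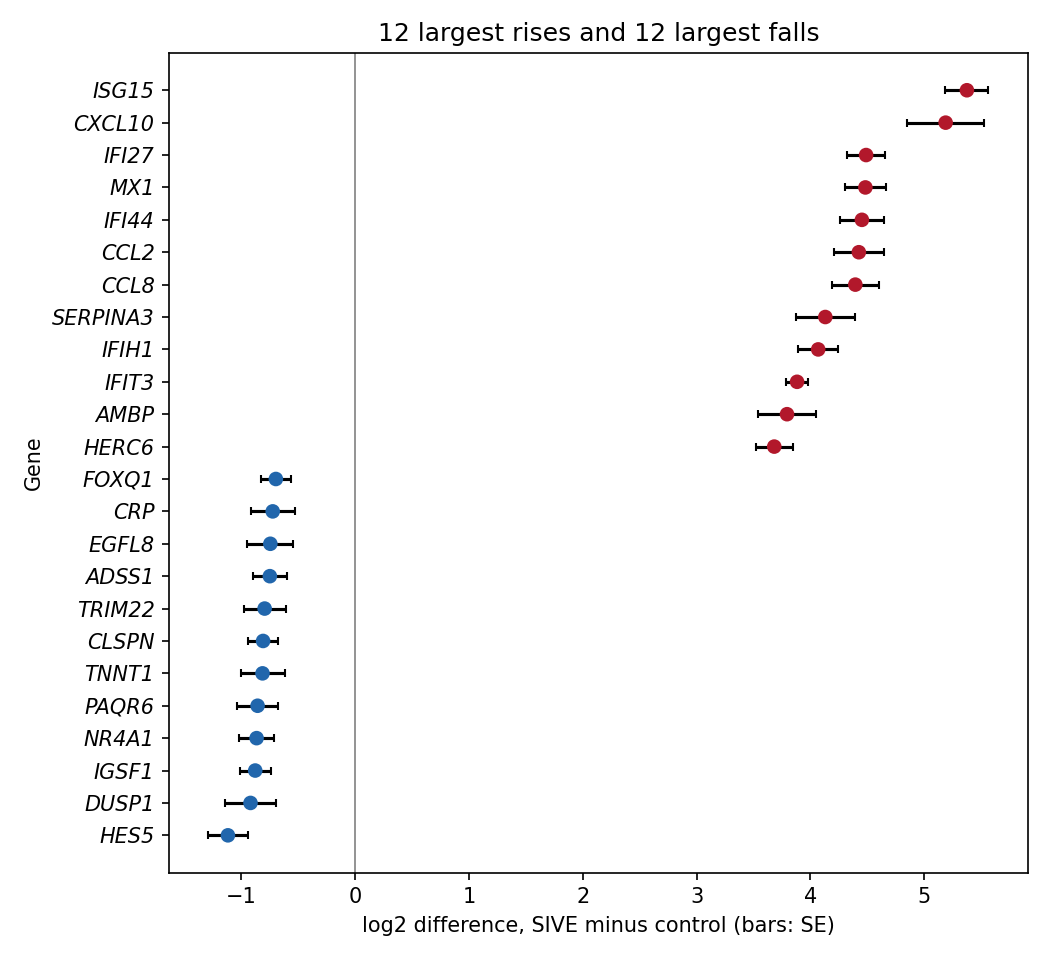
Log2 difference, SIVE minus control, of the 12 genes with the largest rise and the 12 with the largest fall, with bars of 1 SE (9 animals per group). Rises reach 5.37 for ISG15, and the largest fall is -1.12 for HES5.

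A set of 9 probe sets carries 1 nucleotide accession and a coding sequence number in place of a macaque transcript. The sources used here name no organism for them. They are called virus probe sets, on the assumption, from general knowledge, that the accession is that of a simian immunodeficiency virus genome. The probe set of coding sequence 9 was at 9.74 ± 1.27 (SD, n = 9) in SIVE and 3.54 ± 0.32 (n = 9) in controls, a rise of 6.20 ± 0.40 (SE, log2; limma adjusted p = 2.44e-09). Coding sequence 7 rose by 4.31 ± 0.42, coding sequence 8 by 3.62 ± 0.44 and 1 of the 2 probe sets of coding sequence 6 by 2.77 ± 0.37, and in these 4 probe sets all SIVE animals lay above all controls. The controls are uninfected, so if these probe sets read the virus their control signal is background and the differences are lower bounds. Coding sequence 1 rose by 1.31 ± 0.34 (SE, log2, adjusted p = 0.0281) with overlap between the groups, and did not pass with the replicate number as a block or without SIVE 9, Control 3, or the 3 animals of high 3′ signal. The other 4 virus probe sets differed by 0.06 to 0.36 and did not pass. Of 674 further probe sets with such accessions, 0 were higher in SIVE by limma and 9 were lower, with differences from -0.38 to 0.11 over the 674.

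**Figure D3:**
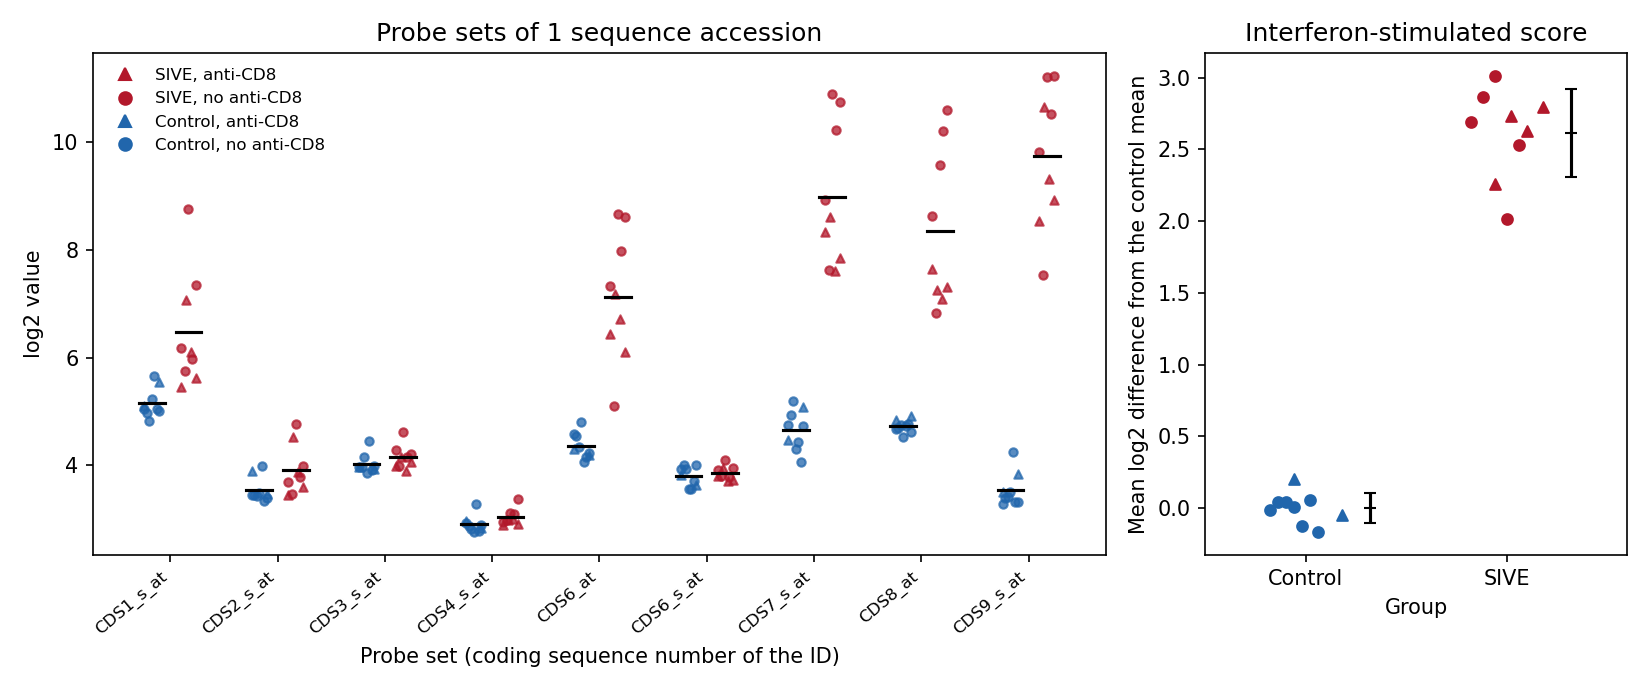
Left, log2 values of the 9 virus probe sets in each animal, with a line at each group's mean (9 SIVE in red, 9 controls in blue, triangles for anti-CD8). Right, the mean log2 difference from the control mean over the interferon-stimulated genes, with mean and SD beside each group. Coding sequence 9 averages 9.74 in SIVE and 3.54 in controls.

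Of 35 measured interferon-stimulated genes, 31 rose and 1, TRIM22, fell (32 and 1 adjusted over the list alone), with a median difference of 2.71 (camera adjusted p = 9.72e-74). That p rests on the preset, low correlation between genes, so its size does not measure the evidence across animals. The same holds for every other p from camera's preset test below. Another split of the animals into groups of the same sizes had 18 lists called by that test, against 16 in the real groups. With an estimated correlation 11 lists were called, 10 higher and 1 lower, and the interferon-stimulated list is among the 10. Besides the genes above, IFIT1 rose by 3.64 and PARP9 by 3.19 ± 0.12 (SE), while OAS1, at 0.25, IFIT2, at 0.22, and DDX60, at 0.03, did not pass. Of 14 measured genes of MHC class I and antigen processing, 12 rose and 0 fell in limma (13 and 0 adjusted over the list alone). Their median was 1.61 (adjusted p = 4.1e-24), and examples are the proteasome subunit PSMB8 at 3.27 ± 0.23, the peptide transporter TAP1 at 2.98 ± 0.15 and the class I regulator NLRC5 at 2.96 ± 0.20. Of 11 measured MHC class II genes, which present antigen in myeloid and B cells, 7 rose and none fell in limma (9 rose adjusted over the list alone), with a median of 1.15 (adjusted p = 1.37e-09). MAMU-DRA rose by 2.83 ± 0.26, IFI30 by 2.38 ± 0.22 and the invariant chain CD74 by 2.06 ± 0.20. Complement, a cascade that tags targets for removal, had 8 of 10 members higher and none lower (9 higher adjusted over the list alone), with a median of 1.90 (adjusted p = 1.19e-13). C1S rose by 2.68 ± 0.20, C1QA by 2.36 ± 0.25 and C1QC by 2.16 ± 0.18.

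Among 26 chemokines and cytokines 11 rose, none fell in limma and 15 did not pass (14 rose and 1 fell adjusted over the list alone), with a median of 0.31 (camera adjusted p = 2.29e-10). TNFSF13B, a B cell survival factor, rose by 2.17 ± 0.19 and CCL3 by 1.94. Retrovirus entry and restriction factors had 5 of 10 members higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.51 (adjusted p = 9.66e-09). BST2, which tethers budding virions, rose by 2.95 ± 0.16, MX2 by 3.15 ± 0.19, IFITM1 by 3.12 ± 0.19 and the cytidine deaminase APOBEC3H by 0.72 ± 0.09. This list shares MX2, TRIM22 and BST2 with the interferon-stimulated genes. Of 9 genes of tryptophan and pterin metabolism 3 rose and none fell, also adjusted over the list alone, with a median of 0.05 (adjusted p = 0.00988). They were IDO1, which breaks down tryptophan, higher by 3.29 ± 0.29 or 9.76-fold, GCH1, which starts pterin synthesis, 3.02-fold higher, and WARS1, a tRNA synthetase, higher by 1.09 ± 0.17.

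Macrophage and myeloid markers had 9 of 19 members higher and none lower in limma (13 higher adjusted over the list alone), with a median of 0.77 (camera adjusted p = 1.37e-09). LYZ rose by 2.71 ± 0.30 (SE), VSIG4 by 2.39 ± 0.26 and PTPRC by 1.52 ± 0.16, while CD68 stood at -0.05 and did not pass. Reactive astrocyte markers had 9 of 14 higher (10 higher and 1 lower adjusted over the list alone), with a median of 0.86 (adjusted p = 2.47e-10). CHI3L1 rose by 2.18 ± 0.25, the cytokine receptor OSMR by 1.42 ± 0.11, CD44 by 1.24 ± 0.11 and the intermediate filament GFAP by 0.36. Of 13 cell cycle genes 7 rose and none fell in limma (9 rose adjusted over the list alone), with a median of 0.45 (adjusted p = 1e-08). TOP2A rose by 1.34, TYMS by 0.86 ± 0.10 and MCM2 by 0.53 ± 0.07.

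Of 8 oligodendrocyte precursor markers 2 fell and none rose in limma (5 fell adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.00778, and 0.0298 with an estimated correlation). SOX11 fell by 0.56 ± 0.12 (SE) and the matrix proteoglycan BCAN by 0.51 ± 0.13. SOX11 is also expressed in young neurons, and BCAN in astrocytes. Immediate early genes, which neurons transcribe within minutes of activity, had 4 of 17 members lower and none higher in limma (5 lower adjusted over the list alone), with a median of -0.30. This list passed camera's threshold with the preset correlation (adjusted p = 0.00204), and passed fry, but the camera call was lost when the correlation was estimated (adjusted p = 0.114 with an estimated correlation). Besides DUSP1 and NR4A1, ARC fell by 0.62 ± 0.15 and NPAS4 by 0.47 ± 0.11. EGR1, which gives the list its name, was not analysed here because no probe set carries that symbol in the table of names used.

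Neuron markers had 2 of 11 members lower and none higher in limma (3 lower adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.0369; adjusted p = 0.308 with an estimated correlation). TUBB3, a neuronal tubulin, fell by 0.51 ± 0.12 (SE) and the synaptic vesicle gene SV2A by 0.27 ± 0.07. Inhibitory neuron markers had 0 of 8 members past the threshold by limma (3 lower adjusted over the list alone), with a median of -0.17 (adjusted p = 0.044; adjusted p = 0.114 with an estimated correlation), and NPY differed by -0.34 ± 0.13. Heat shock and hypoxia genes had 2 of 11 higher (4 higher and 1 lower adjusted over the list alone), with a median of 0.16 (adjusted p = 0.0345; adjusted p = 0.114 with an estimated correlation). These were the co-chaperone BAG3, higher by 0.99 ± 0.08, and ADM, a vasodilator peptide, higher by 1.05 ± 0.16. Endothelial cell and pericyte markers had 4 of 15 higher, also adjusted over the list alone, with a median of 0.06 (adjusted p = 0.0373; adjusted p = 0.439 with an estimated correlation). The adhesion molecule VCAM1 rose by 2.59 ± 0.18, VWF by 0.98 ± 0.24 with no move of its other probe set, PECAM1 by 0.83 ± 0.18 and CDH5 by 0.52 ± 0.12. The score of this list was highest in the animals of high 3′ signal. These were SIVE 3 (0.650) and SIVE 2 (0.506) among SIVE animals and Control 8 (0.418) among controls.

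The remaining 15 lists did not pass the camera test. Among oligodendrocyte markers the myelin gene MBP fell by 0.32 ± 0.07 (SE) and UGT8 by 0.58 ± 0.14 (2 of 10, median -0.26, adjusted p = 0.199; 2 lower and 1 higher adjusted over the list alone). Among astrocyte markers the glutamate transporter SLC1A2 fell by 0.52 ± 0.11 (1 of 11, also over the list alone, median -0.08, adjusted p = 0.338). Of 8 homeostatic microglia markers SLC2A5 rose by 0.94 ± 0.19 (2 higher and 1 lower adjusted over the list alone). The median of that list was -0.13 and its mean -0.01, while the test direction was up (adjusted p = 0.741). Of 14 CD8 and cytotoxic lymphocyte markers GZMB, a protease of cytotoxic cells, rose by 2.36 ± 0.34 (3 higher and 1 lower adjusted over the list alone, median 0.01, adjusted p = 0.537). Of 7 B and plasma cell markers JCHAIN, which joins antibody polymers, rose by 2.81 ± 0.41 (3 higher and 2 lower adjusted over the list alone, median 0.14, adjusted p = 0.453). Of 11 unfolded protein response genes XBP1 rose by 0.31 ± 0.06 and DDIT3 by 0.37 ± 0.10 (2 also adjusted over the list alone, median 0.08, adjusted p = 0.266). Of 20 mitochondrial respiratory chain genes NDUFA4 fell by 0.22 ± 0.05 and COX5A rose by 0.31 ± 0.08 (1 and 1 also adjusted over the list alone, median -0.07, adjusted p = 0.564).

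In the other 8 lists 0 members passed limma's threshold over all probe sets, and, apart from the lists of T cell markers and ribosomal proteins, 0 passed when adjusted over the list alone. T cell markers had a median of -0.08 over 7 genes (camera adjusted p = 0.156; 2 lower adjusted over the list alone). Glutamatergic synapse genes had a median of -0.13 over 13 genes (adjusted p = 0.216), and HOMER1 is on this list and on that of the immediate early genes. The median of 15 cytosolic ribosomal protein genes was 0.00 and the mean -0.01, with the test direction down (adjusted p = 0.681; 2 lower adjusted over the list alone). Choroid plexus and ependyma markers had a median of -0.03 over 7 genes (adjusted p = 0.693), and red blood cell markers -0.08 over 5 (adjusted p = 0.26). Dentate granule cell markers had a median of 0.07 over 6 genes (adjusted p = 0.564), with TDO2 shared with tryptophan metabolism. Pyramidal cell markers of the hippocampus had 0.09 over 4 genes (adjusted p = 0.546), and markers of the neighbouring striatum and thalamus -0.14 over 6 (adjusted p = 0.564).

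**Figure D4:**
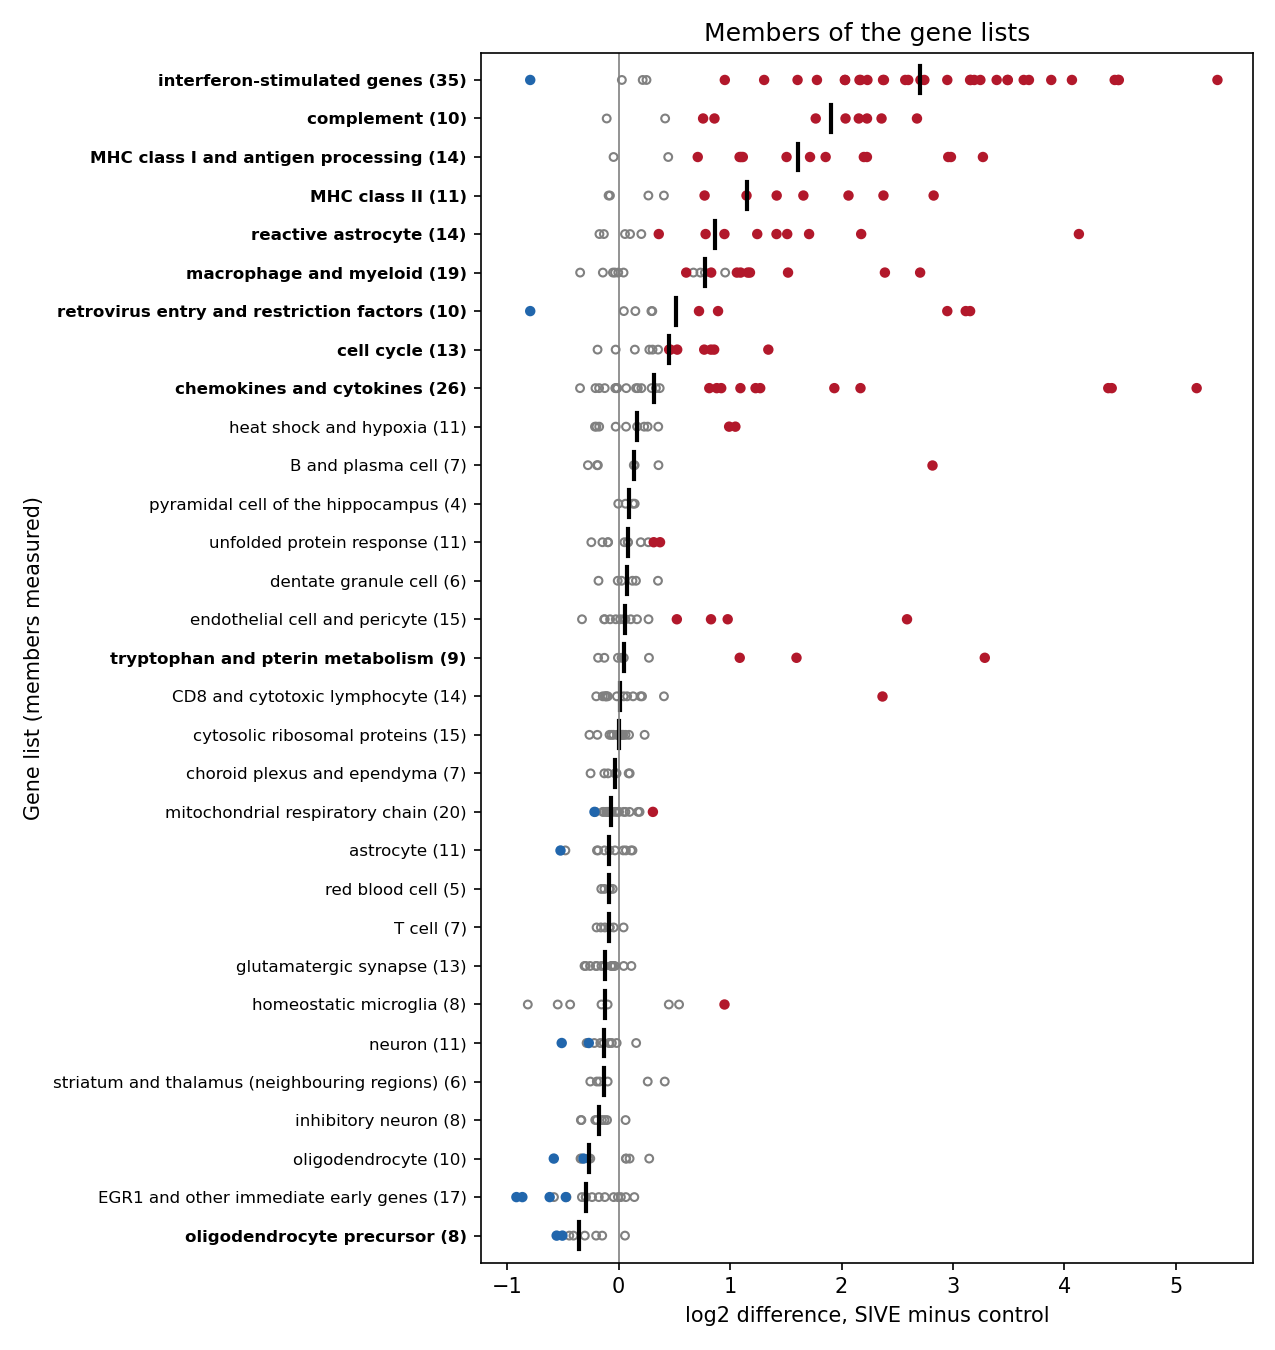
Log2 difference, SIVE minus control, of every measured member of the 31 gene lists, with the list's median as a bar. Filled points passed limma's threshold (red higher, blue lower), and the 11 lists in bold passed the camera test with the preset and with the estimated correlation. The interferon-stimulated list has the highest median, 2.71.

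By limma, 2595 of 52707 probe sets passed, 1912 higher and 683 lower in SIVE, and 520 of them differed by at least 2-fold (515 higher, 5 lower). They include 809 named genes that rose and 213 that fell, and 922 of the probe sets have no gene symbol. At an unadjusted p under 0.05 there were 11199 probe sets, where chance alone would give about 2635. Of the 31 lists 16 passed camera's preset test (12 higher, 4 lower), 11 of the 16 held with an estimated correlation, and all 16 passed fry. The count moved to 5294 (2509 higher, 2785 lower) with the anti-CD8 label as a covariate, 4824 with the 3′ signal difference, 5766 with array weights, 1185 with the probe sets of a gene averaged and 1368 with the replicate number as a block. With array medians set equal the split was 2159 higher and 398 lower.

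In animals without anti-CD8 the comparison of 5 SIVE animals with 7 controls was also led by chemokine and interferon-stimulated genes. CXCL10 rose by 5.87 ± 0.31 (SE, log2), from 4.68 ± 0.22 (SD, n = 7) to 10.55 ± 0.93 (n = 5). ISG15 rose by 5.43 ± 0.23, CCL2 by 4.74 ± 0.25, IFI44 by 4.62 ± 0.24 and IFI27 by 4.58 ± 0.19. HES5 fell by 1.40 ± 0.18, DUSP1 by 1.23 ± 0.26 and PAQR6 by 1.11 ± 0.18 with its other probe set in the opposite direction. SELPLG, an adhesion ligand of microglia and leukocytes, fell by 1.17 ± 0.22, and CFD, complement factor D, by 1.11 ± 0.22. The virus probe set of coding sequence 9 was higher by 6.55 ± 0.50 and that of coding sequence 7 by 5.04 ± 0.43. CD8A differed by -0.02 ± 0.22 and CD8B by -0.03 ± 0.07, and neither passed. Of 35 interferon-stimulated genes 31 rose and 1 fell (median 2.84), and 7 of 10 complement genes rose (median 1.83). Immediate early genes were lower, with 4 of 17 past the threshold and a median of -0.33 (camera adjusted p = 0.000288; adjusted p = 0.0766 with an estimated correlation). By limma 1652 probe sets passed (1235 higher, 417 lower), 501 of them at least 2-fold apart, and 9378 had an unadjusted p under 0.05. Camera called 16 lists (12 higher, 4 lower), of which 10 held with an estimated correlation. The endothelial cell and pericyte list was called up (adjusted p = 0.0443; adjusted p = 0.470 with an estimated correlation) with a median of -0.00 and a mean of 0.32. The count was 2512 without the 3 animals of high 3′ signal, 887 with probe sets averaged and 531 with the replicate number as a block.

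In animals with anti-CD8, 4 SIVE animals were compared with 2 controls, and age is fully separated between them, at 6 years in the SIVE animals and 3 to 4 years in the controls. ISG15 rose by 5.04 ± 0.34 (SE, log2), from 7.21 ± 0.28 (SD, n = 2) to 12.25 ± 0.35 (n = 4). MX1 rose by 4.47 ± 0.35, CCL8 by 4.30 ± 0.40, CXCL10 by 4.29 ± 0.47 and IFI27 by 4.08 ± 0.28. FDXR, a mitochondrial electron transfer protein, fell by 0.93 ± 0.21, GARIN5A by 0.86 ± 0.16, the ciliary gene CC2D2A by 0.68 ± 0.15, UBAP1L by 0.58 ± 0.14 and HMGA2 by 0.51 ± 0.12. Without SIVE 2, SIVE 3 and Control 8, the 3 animals of high 3′ signal, only 2 SIVE animals and 1 control remain in this comparison, and the spread of that control is taken from the other groups. There CC2D2A fell by 0.64 ± 0.20 (SE, log2), FDXR by 0.59 ± 0.21, UBAP1L by 0.54 ± 0.20, GARIN5A by 0.51 ± 0.21 and HMGA2 by 0.37 ± 0.15, and none passed. With so few animals the loss does not tie the falls to the 3′ signal. The virus probe sets of coding sequences 9 and 7 rose by 5.68 ± 0.75 and 3.32 ± 0.64, and that of coding sequence 8, at 2.44 ± 0.64, did not pass (limma adjusted p = 0.0818). CD8A differed by -0.14 ± 0.33 and CD8B by -0.35 ± 0.10, and neither passed. Of 35 interferon-stimulated genes 28 rose and none fell in limma (median 2.58), and 6 of 10 complement genes rose (median 1.63). By limma 555 probe sets passed (445 higher, 110 lower), 352 of them higher by at least 2-fold, and 8186 had an unadjusted p under 0.05. Camera called 12 lists (11 higher, and the oligodendrocyte precursor list lower), and 8 held with an estimated correlation. The count was 187 with age as a covariate, 110 with these 6 animals alone, 12 with the replicate number as a block and 1661 without Control 5. Control 5 is not among these 6 animals, so leaving it out moves the count only through the shared spread.

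Across 14132 genes the SIVE differences in the 2 anti-CD8 classes had a Pearson r of 0.848, a correlation across genes, which are not independent replicates. ISG15, CXCL10 and IFI27 were among 177 genes higher in both classes, out of 514 and 195, where independent lists would share about 7.09. Of 160 and 18 lower genes 2 were shared, against 0.204 for independent lists, and 0 genes passed limma's threshold in opposite directions. The test of the difference itself called 0 probe sets by limma, with a smallest adjusted p of 1.00 and 1481 probe sets at an unadjusted p under 0.05, where chance gives about 2635. This test rests on 2 treated controls, and its median SE was 0.186 (log2), against 0.0885 for SIVE against control over all animals. The simulation did not cover it, so the count of 0 does not show that the 2 effects are equal. CD8A and CD8B differed in their SIVE effect by -0.12 ± 0.39 and -0.32 ± 0.12 (SE, log2) and did not pass. Camera's preset test put 3 lists higher in the SIVE effect with anti-CD8 than without. These were immediate early genes (median 0.20, adjusted p = 0.0129; adjusted p = 0.717 with an estimated correlation), the mitochondrial respiratory chain (0.12, adjusted p = 0.0180; adjusted p = 0.731 with an estimated correlation) and oligodendrocyte markers (0.15, adjusted p = 0.0186; adjusted p = 0.731 with an estimated correlation). None of the 3 passed fry (adjusted p = 0.943 for each). Single animals weigh heavily here. The oligodendrocyte score was 0.396 in SIVE 3 and -0.11, -0.18 and -0.07 in SIVE 1, SIVE 2 and SIVE 4. The mitochondrial score was -0.267 in Control 8 and -0.014 in Control 9, but also low in SIVE 2 (-0.277) and SIVE 3 (-0.140).

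**Figure D5:**
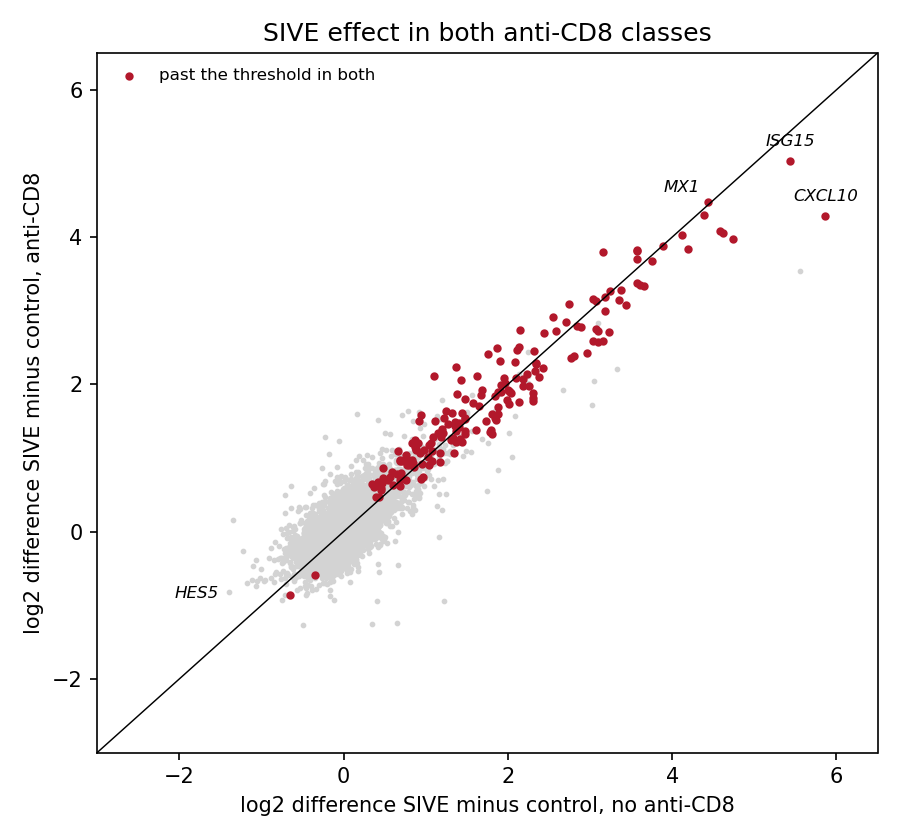
Log2 difference between SIVE and control for 14132 genes in animals with anti-CD8 (4 against 2) against animals without it (5 against 7), with the line of equality. Red points are the genes past limma's threshold in both, 177 of them higher.

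The labels also allow a comparison of anti-CD8 with no treatment among SIVE animals (4 against 5). CD8A was at 6.10 ± 0.27 (SD, n = 4) with anti-CD8 and 6.43 ± 0.46 (n = 5) without, a difference of -0.34 ± 0.25 (SE, log2, limma adjusted p = 0.515). CD8B differed by 0.02 ± 0.08. Among the virus probe sets none passed the threshold adjusted over all 52707 probe sets, though every one had a lower mean with anti-CD8. That of coding sequence 8 differed by -1.84 ± 0.49 (adjusted p = 0.304, unadjusted limma p = 0.00161). That of coding sequence 7 differed by -1.58 ± 0.50 (adjusted p = 0.304, unadjusted limma p = 0.00555). The virus probe sets were not adjusted as a list of their own, so a lower virus signal with anti-CD8 is not excluded. One probe set without a gene symbol, MmugDNA.8752.1.S1_at, was lower with anti-CD8, at 8.76 ± 0.16 (SD, n = 4) against 9.53 ± 0.17 (n = 5), by -0.77 ± 0.09 (adjusted p = 0.00827). It was the only 1 of 52707 probe sets to pass limma, 8079 had an unadjusted p under 0.05, and camera called 0 of 31 lists, as did the estimated correlation and fry. With array weights 3546 probe sets passed, and with all 36 arrays and the animal as a random block 1930. Of the 4 treated animals SIVE 2 and SIVE 3 had the high 3′ signal. Without these 2 and Control 8, 0 probe sets passed limma, 1869 had an unadjusted p under 0.05, and camera called 5 lists (3 higher, 2 lower). Treatment and age are fully separated here, since the treated animals were 6 years old and the others 2 to 5.

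Among controls, 2 animals with anti-CD8 were compared with 7 without. CD8A was at 6.24 ± 0.47 (SD, n = 2) with anti-CD8 and 6.45 ± 0.42 (n = 7) without, a difference of -0.21 ± 0.30 (SE, log2, limma adjusted p = 0.706). CD8B differed by 0.34 ± 0.09 (adjusted p = 0.297), with its other probe set in the opposite direction. Genes of the mitochondrial respiratory chain were lower in camera's preset test (median -0.12, adjusted p = 0.0149; adjusted p = 0.733 with an estimated correlation), and fry did not call the list (adjusted p = 0.438). Camera called 0 lists there with quantile normalization, with the filter on dim probe sets and with the 3′ difference as a covariate. By limma 0 probe sets passed, with a smallest adjusted p of 0.0775 and 8266 at an unadjusted p under 0.05. Of the 2 treated controls Control 8 had the highest 3′ signal and Control 9 the lowest correlation of its duplicates. Without Control 9, 5963 probe sets passed, and Control 8 was then the only treated control, assumed to vary like the other groups. Without Control 5, 769 passed.

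Within the 9 SIVE animals, 4 relations asked whether the interferon-stimulated score, the mean difference from controls over that list, moves with other list scores. For macrophage and myeloid markers Pearson's r was 0.578 (exact permutation p = 0.106, adjusted p = 0.212) and Spearman's rho 0.350 (exact p = 0.359). For reactive astrocyte markers r was 0.660 (exact permutation p = 0.0543, adjusted p = 0.212) and rho 0.467 (exact p = 0.213). Glutamatergic synapse genes gave r = -0.419 (exact permutation p = 0.261, adjusted p = 0.348) and rho = -0.400 (exact p = 0.291). Immediate early genes gave r = 0.125 (exact permutation p = 0.751, adjusted p = 0.751) and rho = 0.183 (exact p = 0.644). Without SIVE 1 and SIVE 8, the animals farthest from the median interferon-stimulated score, r was -0.249 for macrophage, 0.396 for reactive astrocyte, 0.00283 for synapse and 0.742 for immediate early genes (n = 7). With scores centred on the mean of each anti-CD8 class r was 0.673, 0.660, -0.455 and 0.161 in that order, and over all 9 animals no relation passed adjustment. Centred and without SIVE 1 and SIVE 8, immediate early genes gave r = 0.895 (exact permutation p = 0.00417, adjusted p = 0.0167, n = 7), and the other 3 relations did not pass. That relation was seen only with these 2 animals left out.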

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

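Tests of the 3′ signal, the anti-CD8 label, the share of neurons, macrophages and array scaling below were chosen only after the result was seen. For 358 sets of 9 animals (named genes, list scores and array measures), the gap between an extreme animal and its nearest neighbour was divided by the whole range. The ratio passed Dixon's 95% critical value in 47 sets, where chance alone passes about 1 in 20, or 17.9. Control 8 was the far animal in 17 of them, SIVE 9 in 7, Control 5 and SIVE 7 in 5 each, SIVE 8 in 4, Control 7 in 3, SIVE 3 in 2, and Control 2, Control 6, Control 9 and SIVE 2 in 1 each.

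Control 8 lay above the other controls in AMBP (ratio 0.531), NLRC5 (0.645), PSME2 (0.521), BST2 (0.694), ARC (0.545), SELPLG (0.673), CSF1R (0.536), BCAN (0.530), PECAM1 (0.511) and VWF (0.620). It lay below them in HOMER1 (0.512), LYZ (0.510) and NEUROD6 (0.642). Among scores and array measures it was highest in endothelial cell and pericyte markers (0.555), the 3′ minus 5′ difference (0.786) and component 1 (0.635), and lowest in pyramidal cell markers (0.512). The correlation of duplicates was lowest in Control 9 (0.736). Control 5 was high in GZMB (0.528), CNR1 (0.520) and SLC4A5 (0.555) and low in PTPRC (0.567) and WFS1 (0.513). Control 7 was low in MAMU-DMA (0.511) and high in GAP43 (0.504) and the inhibitory neuron score (0.600). Control 2 was high in VSIG4 (0.496) and Control 6 in DDIT3 (0.592).

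SIVE 9 was low in SHANK1 (0.542), CAMK2B (0.698), NRGN (0.613), TUBB3 (0.517) and ATF3 (0.534), and high in NDUFA4 (0.498) and KCNJ13 (0.673). Its neuron score (-0.18) and glutamatergic synapse score (-0.07) lay within the range of the other SIVE animals. Its pyramidal cell score (0.59) was the highest of all animals. SIVE 8 was low in MX1 (0.531), HERC6 (0.498), SLC2A5 (0.656) and CD53 (0.504). SIVE 7 was high in WARS1 (0.494), DNAJB1 (0.497), CLIC6 (0.759), the chemokine and cytokine score (0.5681) and the choroid plexus and ependyma score (0.676). SIVE 3 was high in MBP (0.569) and the oligodendrocyte score (0.618), and SIVE 2 in ALAS2 (0.522).

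In 3 lists the SIVE effect differed between the anti-CD8 classes by camera's preset test: immediate early genes (adjusted p = 0.0129), mitochondrial respiratory chain (adjusted p = 0.0180) and oligodendrocyte markers (adjusted p = 0.0186). With an estimated correlation the adjusted p were 0.717, 0.731 and 0.731, and fry gave 0.943 for each.

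SIVE 2, SIVE 3 and Control 8 stood apart on component 1. Anti-CD8 treatment alone is argued against, since all 3 of the other animals labelled anti-CD8 lay within the range of the animals without it. A 3′ shift of the RNA may account for the place of these animals, since the 3 highest on component 1 were the 3 with the highest 3′ minus 5′ difference, measured on probe sets outside the component. The 2 SIVE animals with a 3′ shift are also a candidate explanation for the many small unadjusted p-values of the anti-CD8 label in SIVE animals: without SIVE 2 and SIVE 3 there were 1284, while each other pair of treated animals left out gave 3649 to 15696. A biological difference of these animals, such as the treatment acting in some of them, stays open and untested.

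The immune lists rose together in SIVE. Array scaling was checked with quantile normalization, where 12 lists were called higher, as with the deposited values. The deposited values were already normalized between arrays, and camera compares a list with other genes. The count could thus hardly move, and it does not decide on array scaling. A lower share of neurons alone would raise the markers of every other cell type alike. The oligodendrocyte precursor list was instead called lower, with a median of -0.36 (camera adjusted p = 0.0298 with an estimated correlation). But SOX11, a member of that list past the threshold, is also expressed in young neurons, so this list alone does not decide the question. The sizes argue against fewer neurons as the sole cause of the interferon-stimulated rise. That list had a median of 2.71, while astrocyte and oligodendrocyte markers had medians of -0.08 and -0.26, and neuron markers -0.13. A part in the smaller rises stays open. More macrophages could account for part of the rise: the interferon-stimulated score had r = 0.578 with the macrophage and myeloid score over 9 SIVE animals (exact permutation p = 0.106), too few animals to decide. Spearman's rho was 0.350 (exact permutation p = 0.359), and without SIVE 1 and SIVE 8 r was -0.249. A response of the resident cells to infection or to encephalitis stays open beside more macrophages, and the design does not separate these.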

How the results depend on the processing

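The 3 settings on 3′ signal and on Control 9 were chosen only after the data were seen. Of 5985 alternative values for 178 named genes and virus probe sets, 5697 kept their direction and side of the threshold, 169 lost it, 118 passed newly and 1 reversed: TRIM22, from -0.79 to 0.64, with the probe sets of a gene averaged, since its other probe set moved the opposite way. Of the 24 largest changes 18 passed in 1 direction under all 34 alternatives run. Of 899 values for the 31 lists in SIVE against control 862 kept, 35 lost and 2 gained a call, and 11 of 16 called lists passed under every setting run. The called count was 13 to 16 with single animals left out and 11 with an estimated correlation, and over all 9 SIVE animals no call of the 4 relations changed. Where no cause is given below, the cause was not tested.

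Averaging the probe sets, which tests fewer items, gave 1185 calls for SIVE against control (183 at least 2-fold apart), 887 without anti-CD8, 269 with it and 0 for anti-CD8 in SIVE animals. Array weights gave 5766, 4428 and 135 for the same first 3 comparisons and 3546 for anti-CD8 in SIVE animals. The 36 arrays with the animal as a random effect gave 3197 without anti-CD8, 1043 with it, and 1930 and 9 for anti-CD8 in SIVE and control animals. Only technical replicate 2 arrays gave 979 with anti-CD8, 0 for anti-CD8 in SIVE animals and 284 in controls. The anti-CD8 label as a covariate gave 5294 for SIVE against control, and with age 4957, and 47.4% and 48.6% of these were higher against 73.7% in the main result. Age alone as a covariate gave 187 with anti-CD8. Quantile normalization and the filter on dim probe sets each gave 1 call for anti-CD8 in controls. Only the animals compared gave 110 with anti-CD8 and 0 for anti-CD8 in SIVE animals. Without the 3 animals of high 3′ signal there were 2512 calls without anti-CD8, 205 with it (2 SIVE animals against 1 control, too few to lay the change on the 3′ signal) and 0 for anti-CD8 in SIVE animals, and with the 3′ difference as a covariate 4824 for SIVE against control, 2670 without anti-CD8 and 950 with it.

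With the replicate number as a block the counts were 1368 for SIVE against control, 531 without anti-CD8, 12 with it, 2 for the difference between them, and 0 and 4 for anti-CD8 in SIVE and control animals. The numbers do not pair the animals: residuals of the 9 pairs correlated between -0.488 and 0.0888, 0 of 9 above 0.1, and for 0 SIVE animals was the control of its own number the best match.

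Leaving out each animal in turn gave 2055 to 3013 calls for SIVE against control (496 to 562 at least 2-fold apart), 1119 to 2015 without anti-CD8, 355 to 1661 with it, 0 to 0 for the difference, 1 to 4 for anti-CD8 in SIVE animals and 0 to 5963 in controls. An animal outside a comparison acts on its count only through the shared spread. With anti-CD8 the count was 355 without SIVE 4 and 1661 without Control 5, which is such an animal. For anti-CD8 in SIVE animals it was 2 without SIVE 2, SIVE 4 or SIVE 7 and 4 without SIVE 6. In controls it was 5963 without Control 9, 769 without Control 5, 3 without SIVE 2 and 1 without SIVE 4. Dim probe sets lie near background, and the 1883 calls at or above the median level come from a smaller set of tests.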

Other observations

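The test of the virus score by anti-CD8 label, and the probe sets of that score, were chosen only after the result was seen; the relations of the virus score and the counts over other splits were chosen before theirs were. Virus probe sets varied widely among SIVE animals. The virus score, over the 5 virus probe sets called higher in SIVE (coding sequences 1, 7, 8 and 9 and 1 probe set of coding sequence 6), was 3.64 ± 1.16 (SD, n = 9) in SIVE, from 2.08 in SIVE 6 to 5.32 in SIVE 7, against a control range of -0.22 to 0.23, and the choice of probe sets by this same difference makes it no separate test of the groups. The interferon-stimulated score of the same 9 animals ran from 2.02 in SIVE 8 to 3.01 in SIVE 7. SIVE 8 thus had the lowest interferon-stimulated score and a virus score of 4.48, and SIVE 6 had the lowest virus score and an interferon-stimulated score of 2.86.

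The virus level among SIVE animals was set against 3 explanations. The interferon response may follow the virus level, but r between the scores was -0.0827 over 9 animals (exact permutation p = 0.835, rho = -0.150 with exact p = 0.708, r = -0.327 without SIVE 6 and SIVE 7). Macrophage markers may follow it, but r was -0.0188 (exact permutation p = 0.952, rho = -0.100 with exact p = 0.810, r = -0.312 without the same animals). The adjusted p was 0.952 for both of these 2 relations. Anti-CD8 treatment may change the virus level: the score was 3.00 ± 0.45 (SD, n = 4) with it and 4.16 ± 1.33 (n = 5) without (exact permutation p = 0.119). With 9 animals these tests leave all 3 explanations open.

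Other splits of the animals into groups of the same sizes were counted over 100 splits, the real one included. Chance can be excluded for SIVE against control, where only the real split, 1 of 100, gave as many as 2595 calls and the highest other gave 1, and for its 520 calls of at least 2-fold, where the highest other gave 0. It can be excluded for the 1652 calls without anti-CD8, where the highest other split gave 4. For the 16 called lists 2 of 100 splits gave as many, the real one included, and the other gave 18. That share is under the 0.05 level, but 1 other split passed the real count. Chance is therefore not excluded for lists called only with the preset correlation. For the 11 lists called with an estimated correlation the highest other split gave 1, and chance can be excluded for that count. Since another split did call 1 list, the count does not exclude chance for each list alone. Chance cannot be excluded for the 1 call of anti-CD8 in SIVE animals, where 15 of 100 splits gave as many and the highest other gave 4. Leaving out SIVE 1 and SIVE 4, so that SIVE 2 and SIVE 3 alone stood for anti-CD8, gave 6727 calls, which points to a structure of the samples. These 2 animals differ from the untreated SIVE animals in 3′ signal, anti-CD8 label and age alike, and the count does not separate these.

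Array medians differed between the groups by -0.03 (log2; exact permutation p = 0.0213), with 5.62 ± 0.02 (SD, n = 9) in SIVE and 5.65 ± 0.02 (n = 9) in controls. The 158 control and reporter probe sets differed by -0.40 to 0.15, with a smallest limma adjusted p of 0.0723.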
